A study of Trichoderma cf. simile with 24 samples.

How the data were processed

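RNA was measured in 24 samples of mycelium of Trichoderma cf. simile WF8 from flask cultures, 3 for each of 4 culture types at days 1 and 3 after addition. Flask numbers recur at both days, and the labels do not say whether a flask was sampled at both. Per the labels, cultures were grown for 60 h in the dark in 100 mL of Sabouraud maltose broth (maltose 40 g/L, peptone 10 g/L) in 250 mL flasks at 180 rpm and 29 °C, and then received a lignite model compound. The treatment text also lists copper, manganese and veratryl alcohol as additions. Whether the control received these or dichloromethane is not given in the sources used here. Poly-A RNA was converted into libraries with fragments of 370 to 420 bp and sequenced as paired reads of 150 bp, per the labels.

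The deposited files hold raw read counts per gene and FPKM values for the same 24 libraries. Per the submitters' processing notes, the authors counted reads with featureCounts 1.5.0-p3; the aligner, the genome build and the annotation are not given in the sources used here. The count table lists 13298 loci, 12486 of them numbered gene models and 812 loci outside these models, and 570 loci had 0 counts in all libraries. The deposited FPKM were checked against the counts: they equal counts divided by a gene length and by a library size scaled with a median-of-ratios factor, and all 12728 lengths recovered this way were whole numbers within 0.01. The median length was 1458 bp and 69.6% of lengths were multiples of 3. The files pair 0 gene IDs with a name or description, and no reference annotation was used, so the gene lists drawn up before the data were examined, among them a list of conidiation genes, could not be scored.

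Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by filterByExpr with a minimum count of 10 over the 8 groups, which left 10842 loci, 645 of them outside the numbered models. Libraries were scaled by TMM, and a quasi-likelihood negative binomial model with a coefficient per group was fitted to all 24 libraries together, because 3 flasks per group give few residual degrees of freedom. Contrasts were tested with the quasi-likelihood F test, which covers both directions, and p-values were adjusted by the Benjamini-Hochberg method within each contrast; a gene was called at an adjusted p under 0.05. The contrasts were each compound against the control at each day, day 3 against day 1 in each culture type, the difference of that change from the control's, and the compounds against each other at each day, 19 in all. The groups, the contrasts, the test, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

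Genes were named by a fixed rule. For each compound, among genes called in the same direction at both days, with groups that did not overlap and at least 10 counts in every library of the higher group, the 2 with the largest mean rise and the 2 with the largest mean fall were taken. The same rule gave 2 and 2 genes for the time course of the control. For phenetole 43 genes that rose and 30 that fell met the conditions, for 4-phenoxybenzoic acid 2 and 2, for 9,10-dibutoxyanthracene 123 and 496, and for the control time course 947 and 1053. Thus all 3 libraries of the compound lay beyond all 3 control libraries for each gene so named. Folds are ratios of counts pooled over a group and scaled by library size. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is given as a lower bound; against 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

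The overlap of calls between compounds was set against independent lists of the same sizes and against 20 data sets simulated with unchanged groups that share the same control libraries. Genes were simulated independently, without correlation between genes and without deviations shared by flasks of the same number. The position along the control time course was the slope of a library's log2 differences from the day 1 control on the control's day 3 to day 1 change, over the 2251 genes called in the control; each control library was placed on an axis made without it. Groups were compared by exact two-sided permutation tests. Correlations between libraries of the same group over genes were 0.933 to 0.985. The labels do not say that the flasks were separate cultures sampled once, so p-values measure the spread between these samples.

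The methods were tested on data simulated for all 24 libraries from the fitted model. For the test, the 4-phenoxybenzoic acid group of day 1 was given the control means of that day, apart from the changed genes. With 200 of 10842 genes changed, the test recovered 66.2% of genes changed 4-fold and 15.6% of those changed 2-fold, and 5.3% of calls were false. Simulated positions of 0, 0.5 and 1 were estimated as 0.06, 0.49 and 0.94. In these data all groups shared a spread estimate per gene, genes were independent, and flasks shared no deviations. The real groups differed in spread and flasks of the same number deviated together, so the error rate in the real data may differ from 5.3%.

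Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, limma 3.58.1 with a trend on log2 of deposited FPKM plus 1 or plus 0.1, a fit of the compared groups alone, the flask number or the flask as a block, and each library left out in turn. The position was also computed over all tested genes, and the overlap also from DESeq2 calls. Added after the data were seen were fits without the flasks numbered 3, a position from separate control libraries, a position without the 100 most abundant genes, and tests of day 1 cultures with a compound against the day 3 control. Other splits of the same libraries were fitted the same way and their called genes counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.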

Results

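Gene expression was measured by RNA sequencing in mycelium of the filamentous fungus Trichoderma cf. simile WF8, grown in shaken flasks with or without a lignite model compound. Lignite is brown coal, and the model compounds are small aromatic molecules that carry bond types found in it. The 3 compounds were phenetole (ethoxybenzene, an alkyl aryl ether), 4-phenoxybenzoic acid (a diaryl ether with a carboxylic acid) and 9,10-dibutoxyanthracene (an anthracene carrying butoxy groups). With butoxy groups on an aromatic ring, 9,10-dibutoxyanthracene is an alkyl aryl ether too. Together with the control, and with sampling 1 or 3 days after addition, they formed 8 groups of 3 flasks, 24 libraries in all. The final doses were 200 mg/L phenetole, 10 mg/L 4-phenoxybenzoic acid and 5 mg/L 9,10-dibutoxyanthracene. Phenetole was added neat, while the other compounds were added from stocks in dichloromethane, which by their strength made up 5% and 2.5% of the culture volume. Total counts per library ranged from 16767477 to 19842379, and between 10894 and 11633 of the 13298 listed loci had at least a single count in a library. The sources used here pair 0 of the gene IDs with a name or a function, so genes are given by ID, and no gene group, conidiation markers included, could be scored. Values are mean ± SD of 3 flasks in CPM, counts scaled to a common library size, and log2 changes carry ± SE.

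The most abundant transcript, Trisim1_000288 (908 bp), a locus singled out after its values were seen, took 5.30% ± 0.749 of all counts in control cultures at day 1 (SD, n = 3). With 9,10-dibutoxyanthracene it took 2.58% ± 0.519 at day 1 and 0.592% ± 0.0835 at day 3, against 2.48% ± 0.62 in the day 3 control. Its normalized level with this compound fell by 1.32 ± 0.46 on the log2 scale at day 1 (adjusted p = 0.0309, edgeR) and by 2.01 ± 0.46 at day 3 (adjusted p = 0.00738). With phenetole at day 1 it took 3.68% ± 0.553 of counts, while its normalized log2 difference from the control was −0.07 ± 0.45 (adjusted p = 0.922, edgeR). The TMM factors averaged 0.67 with phenetole and 0.937 in the control at day 1, so a like normalized level there goes with a lower share. Phenetole cultures at day 1 had the fewest loci with a count, 10946 ± 46.1 per library against 11307 ± 79.4 in the control of that day.

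**Figure D1:**
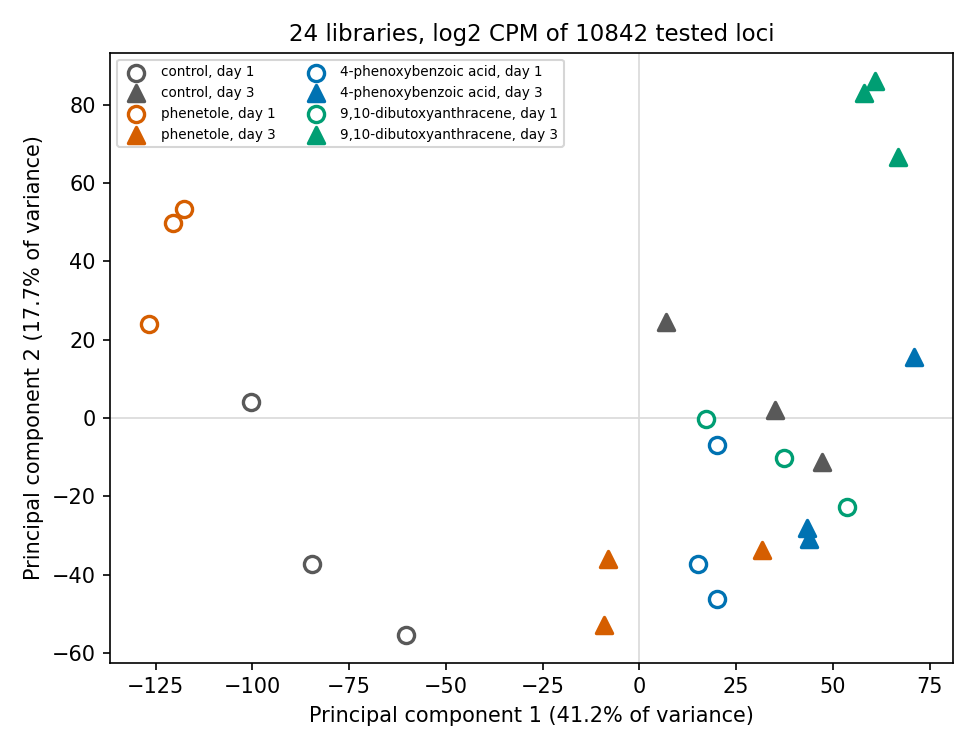
Principal component scores (no unit) of the 24 libraries, from log2 CPM of the 10842 tested loci; each point is a library, the colour gives the culture type, and open circles and filled triangles are days 1 and 3. Component 1 (41.2% of the variance) ran from phenetole cultures at day 1 (−126.8 to −117.8) and control cultures at day 1 (−100.3 to −60.42) at its low end to cultures of day 3 with 9,10-dibutoxyanthracene (57.91 to 66.92) and with 4-phenoxybenzoic acid (43.38 to 71) at its high end.

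With phenetole, the question was which genes respond to a simple alkyl aryl ether. Trisim1_006099 (462 bp) and Trisim1_006100 (384 bp), neighbours in the gene numbering, rose most among the genes that rose at both days. Trisim1_006100 stood at 376 ± 42.8 CPM at day 1 and 196 ± 49.3 CPM at day 3 (SD, n = 3), against 0.145 ± 0.172 and 0.35 ± 0.375 CPM in the controls, ratios of 2380-fold and 530-fold. Trisim1_006099 reached 30.9 ± 4.06 and 26.8 ± 11.8 CPM. The day 1 controls held 2 counts of it in all, a 777-fold ratio with a counting interval of 215 to 6420, and the day 3 controls held 0, so it was at least 506-fold higher. Trisim1_003502 (6492 bp) and Trisim1_003601 (1515 bp) fell most. Trisim1_003502 fell from 10.1 ± 6.83 to 0.287 ± 0.289 CPM at day 1, 33.6-fold, and from 9.9 ± 8.34 to 0.143 ± 0.161 CPM at day 3, 68.9-fold. Trisim1_003601 fell 70.4-fold at day 1 (counting interval 23.9 to 343; 3 counts with phenetole) and 30.8-fold at day 3.

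At day 1 the edgeR quasi-likelihood test called 2988 of 10842 loci with phenetole, of which 1337 rose and 1651 fell, and 2127 of them differed at least 2-fold. At day 3 it called 371, of which 165 rose and 206 fell. Adjusted p-values (edgeR) of Trisim1_006100 were 9.48e-06 and 0.00029 at the days, those of Trisim1_006099 0.000422 and 0.00251, those of Trisim1_003502 0.00274 and 0.00604, and those of Trisim1_003601 0.0113 and 0.0323. Of 14 alternatives, the day 3 call was lost in 6 for Trisim1_003601, 3 for Trisim1_003502 and 1 for Trisim1_006099, and the day 1 call of Trisim1_003601 in 2. Of the called genes, 45 rose at both days against 20.3 from independent lists, 35 fell at both days against 31.4, and 33 changed in opposite directions. The day 1 count was 609 with only the compared groups in the fit and 1869 without control flask 2. These groups had the widest spread at day 1, with a median SD over genes of 0.495 with phenetole and 0.485 in the control (log2 CPM). The day 3 count was 678 with the flask number as a block, 11 with only the compared groups, and 82 without phenetole flask 3.

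**Figure D2:**
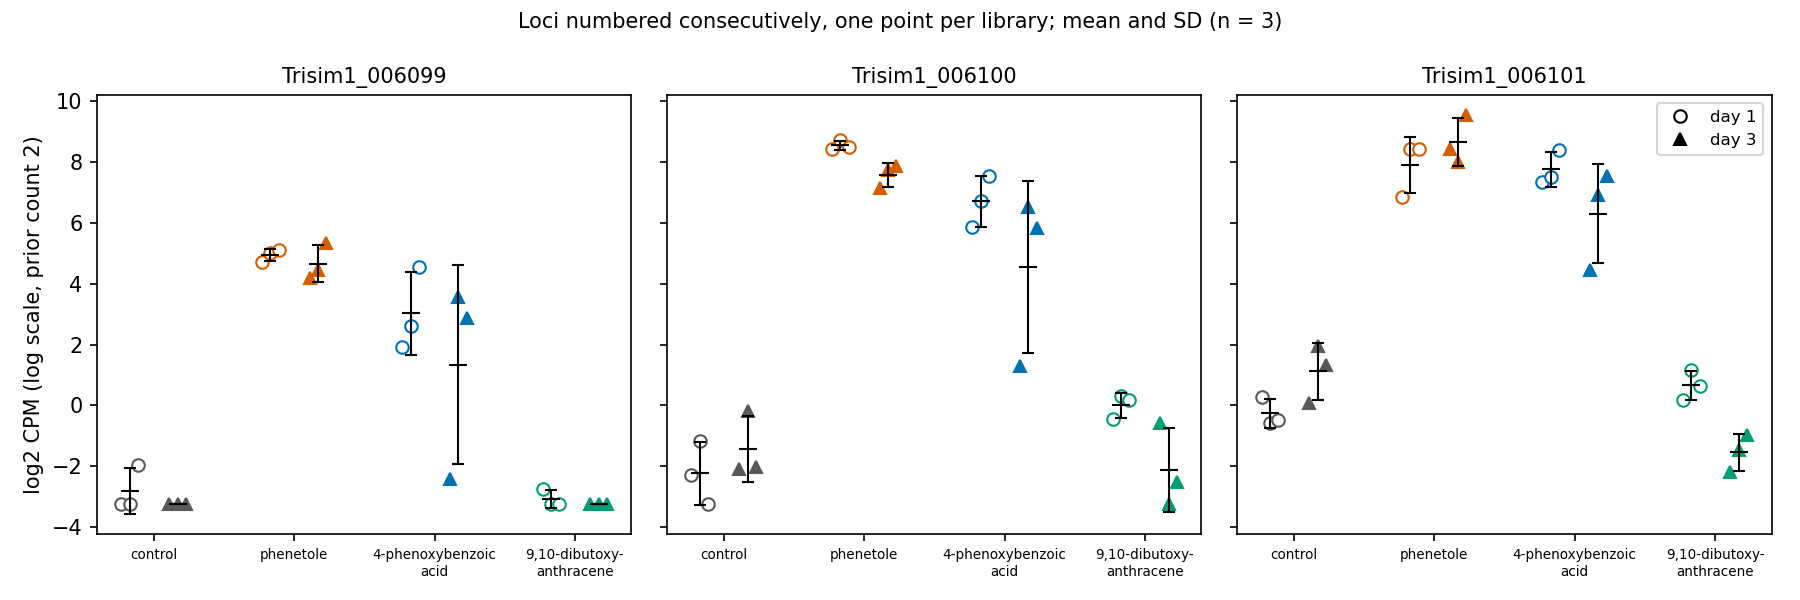
log2 CPM (log scale, prior count 2) of 3 consecutively numbered loci in each of the 24 libraries; points are libraries, bars are mean and SD of 3 flasks, and open circles and filled triangles are days 1 and 3. Trisim1_006100 reached 376 ± 42.8 CPM with phenetole and 116 ± 63.6 CPM with 4-phenoxybenzoic acid at day 1, against 0.925 ± 0.267 CPM with 9,10-dibutoxyanthracene and 0.145 ± 0.172 CPM in the control.

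With 4-phenoxybenzoic acid, a diaryl ether, Trisim1_006100 and its numbered neighbour Trisim1_006101 (4518 bp) rose at both days. Trisim1_006101 reached 228 ± 94.8 CPM at day 1 and 109 ± 82 CPM at day 3 (SD, n = 3), against 0.76 ± 0.3 and 2.36 ± 1.38 CPM in the controls, ratios of 289-fold and 47.5-fold. Trisim1_006100 reached 116 ± 63.6 and 50.5 ± 45.3 CPM, ratios of 732-fold and 138-fold, and at day 3 its libraries ranged from 2.37 to 92.4 CPM. Trisim1_010012 (3893 bp) fell 6.84-fold at day 1, to 26.5 ± 11.9 from 188 ± 80.7 CPM, and 9.58-fold at day 3, to 11.4 ± 4.13 from 112 ± 62.2 CPM. Trisim1_003741 (1107 bp) fell 3.45-fold and 5.24-fold, to 67.4 ± 10.1 and 31.7 ± 4.65 CPM. Trisim1_006099 was 276-fold higher at day 1 (counting interval 76.2 to 2290; adjusted p = 0.001, edgeR), while at day 3 it stood at 6.38 ± 5.9 CPM against 0 counts in the control, at least 122-fold, and did not pass the test (adjusted p = 0.0626).

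The edgeR test called 2601 genes with 4-phenoxybenzoic acid at day 1, of which 1143 rose and 1458 fell, and 8 at day 3, where 4 rose and 4 fell. At day 3, besides the loci above, Trisim1_002131 rose by 1.83 ± 0.32 (adjusted p = 0.0275) and Trisim1_011706 by 1.92 ± 0.35 (adjusted p = 0.0395) on the log2 scale. Trisim1_004314 fell by 3.8 ± 0.73 (adjusted p = 0.049) and Trisim1_009862 fell by 3.35 ± 0.59 (adjusted p = 0.0275); these 4 loci were named after their values were seen. Adjusted p-values (edgeR) at the days were 2.52e-06 and 0.00174 for Trisim1_006101, 1.16e-05 and 0.005 for Trisim1_006100, 0.00202 and 0.0451 for Trisim1_010012, and 0.00194 and 0.0239 for Trisim1_003741. Of 14 alternatives, the day 3 call was lost in 8 for Trisim1_010012, 7 for Trisim1_003741, 3 for Trisim1_006100 and 2 for Trisim1_006101, and the day 1 call of Trisim1_003741 in 1. At day 3, 1093 genes had an unadjusted p under 0.05, DESeq2 called 181 (21 rose, 160 fell), a fit with the flask number as a block called 133 (10 rose, 123 fell), and edgeR called 0 both with the compared groups alone (1114 at an unadjusted p under 0.05) and without flasks numbered 3 (540). The day 1 count was 1704 without 4-phenoxybenzoic acid flask 1 and 1285 without flasks numbered 3. Leaving out a single library moved the day 3 count to between 1 (without control flask 3) and 81 (without control flask 1).

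With 9,10-dibutoxyanthracene, an anthracene with butoxy groups, Trisim1_002817 (3703 bp) and Trisim1_001031 (1413 bp) rose most among the genes that rose at both days. Trisim1_002817 stood at 18.9 ± 6.93 CPM at day 1 (SD, n = 3) against 2 counts over the control libraries, a 475-fold ratio (counting interval 131 to 3930), and at 39.3 ± 9.92 against 7.14 ± 1.06 CPM at day 3, 5.75-fold. Trisim1_001031 stood at 26.2 ± 32.2 against 0.117 ± 0.203 CPM at day 1, 201-fold, with libraries between 3.25 and 63 CPM, and at 404 ± 19.4 against 58.6 ± 33.3 CPM at day 3, 6.4-fold. Trisim1_008178 (1404 bp) fell 96.6-fold at day 1, from 86.6 ± 3.85 to 0.883 ± 0.975 CPM, and 6.08-fold at day 3. Trisim1_007510 (2654 bp) fell 88.1-fold at day 1, from 20.9 ± 10.1 to 0.211 ± 0.151 CPM, and 12.7-fold at day 3. At day 1 Trisim1_002817 also rose 11400-fold with 4-phenoxybenzoic acid (counting interval 3170 to 94500) and 2830-fold with phenetole (783 to 23400). Its adjusted p-values (edgeR) were 9.8e-07 and 5.7e-06. Trisim1_008178 fell 19.2-fold and 35.2-fold with these compounds at day 1 (adjusted p = 0.00105 and 0.000496). Trisim1_001031 rose and Trisim1_007510 fell with 4-phenoxybenzoic acid (adjusted p = 0.000897 and 0.00026) but did not pass with phenetole (0.757 and 0.0968). Trisim1_006101, which rose with both other compounds, fell by 3.19 ± 0.84 on the log2 scale with 9,10-dibutoxyanthracene at day 3 (adjusted p = 0.0146, edgeR) and differed by 0.98 ± 0.73 at day 1 (adjusted p = 0.327).

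The edgeR test called 3442 genes with 9,10-dibutoxyanthracene at day 1, of which 1611 rose and 1831 fell, and 1740 at day 3, of which 568 rose and 1172 fell. The balance of directions at day 3 moved with the method, with 949 rising and 1396 falling by DESeq2 and 939 rising and 1011 falling by limma on log2(FPKM + 1). Adjusted p-values (edgeR) at the days were 1.54e-05 and 0.0217 for Trisim1_002817, 0.00019 and 0.0373 for Trisim1_001031, 3.16e-05 and 0.0495 for Trisim1_008178, and 1.17e-05 and 0.00888 for Trisim1_007510. Of the called genes, 551 fell at both days against 198 from independent lists, 139 rose at both days against 84.4, and 116 changed in opposite directions. The day 1 count was 2209 with only the compared groups in the fit. The day 3 count was 729 without 9,10-dibutoxyanthracene flask 2, 799 without its flask 3 and 907 without control flask 2, and of 14 alternatives the day 3 call was lost in 9 for Trisim1_008178, 8 for Trisim1_001031, 5 for Trisim1_007510 and 3 for Trisim1_002817.

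**Figure D3:**
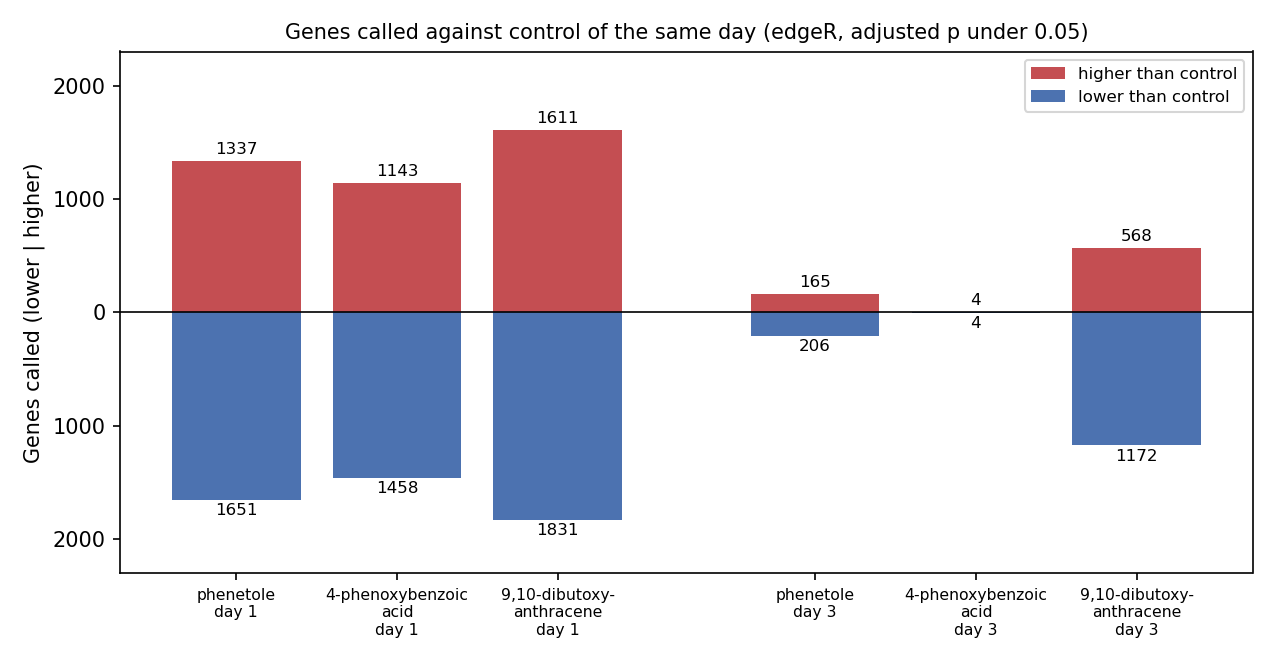
Number of genes called by the edgeR quasi-likelihood test (adjusted p under 0.05) for each compound against the control of the same day, with 3 libraries per group; bars above 0 are genes that rose and bars below 0 are genes that fell. At day 1 the totals were 2988 with phenetole, 2601 with 4-phenoxybenzoic acid and 3442 with 9,10-dibutoxyanthracene, and at day 3 they were 371, 8 and 1740.

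Between day 1 and day 3 the control cultures themselves changed. Trisim1_003562 (429 bp) rose from a single count over the day 1 libraries to 42.3 ± 10.4 CPM (SD, n = 3), 2070-fold (counting interval 371 to 81700), and Trisim1_003296 (632 bp) rose from 0 counts to 11.2 ± 4.19 CPM, at least 200-fold. Trisim1_007370 (759 bp) fell from 3.53 ± 2.08 CPM to 0 counts, at least 72.3-fold lower, and Trisim1_009558 (2304 bp) fell from 3.06 ± 1.27 CPM to 0 counts, at least 57.4-fold lower. Their adjusted p-values (edgeR) were 2.52e-08, 0.000849, 0.000685 and 0.000243. Trisim1_002817 also rose with time in the control, 178-fold (counting interval 48.9 to 1470; adjusted p = 0.000177), and Trisim1_008178 fell 19.7-fold (adjusted p = 0.000849). Trisim1_001031 rose 456-fold (adjusted p = 8.06e-05, edgeR) and Trisim1_007510 fell 8.91-fold (adjusted p = 0.00203). Thus each gene named for 9,10-dibutoxyanthracene moved with time in the control in the direction it moved with the compound.

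The edgeR test called 2251 genes for day 3 against day 1 in the control, of which 1097 rose and 1154 fell. In the cultures with a compound it called 4936 with phenetole (2586 rose, 2350 fell), 2354 with 9,10-dibutoxyanthracene (1089 rose, 1265 fell) and 329 with 4-phenoxybenzoic acid (197 rose, 132 fell). The count with 4-phenoxybenzoic acid was 409 with flasks as blocks, 731 with DESeq2, 30 without its day 1 flask 1 and 43 without its day 1 flask 2. The control count was 1228 with only the compared groups in the fit. With 9,10-dibutoxyanthracene the count was 1358 without its day 3 flask 3, 1404 without its day 1 flask 2 and 1500 without its day 3 flask 2.

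At day 1, genes of the control time course already differed from the control in cultures with 4-phenoxybenzoic acid or 9,10-dibutoxyanthracene, the compounds added in dichloromethane. Trisim1_003562 stood at 18.5 ± 7.49 and 33.3 ± 11.9 CPM with these compounds (SD, n = 3; adjusted p = 1.38e-07 and 4.7e-08, edgeR), and at 0.0275 CPM, a single count, with phenetole (adjusted p = 0.892). Trisim1_003296 was at least 44.5-fold and 85.5-fold higher with these compounds than in the day 1 control (adjusted p = 0.00687 and 0.00194). Trisim1_007370 was 122-fold lower with 4-phenoxybenzoic acid (counting interval 33.2 to 1010; adjusted p = 0.00123) and at least 78.8-fold lower with 9,10-dibutoxyanthracene (adjusted p = 0.000408). Trisim1_009558 was 193-fold lower with 4-phenoxybenzoic acid (counting interval 34.2 to 7690; adjusted p = 0.000423) and 37.6-fold lower with 9,10-dibutoxyanthracene (adjusted p = 0.000917). With phenetole these genes fell as well, Trisim1_007370 6.73-fold (adjusted p = 0.0352) and Trisim1_009558 9.73-fold (adjusted p = 0.0151). Of the 1097 genes that rose with time in the control, 845 (77%) also rose with 9,10-dibutoxyanthracene at day 1, 624 (56.9%) with 4-phenoxybenzoic acid and 169 (15.4%) with phenetole. Of the 1154 that fell with time, 955 (82.8%), 768 (66.6%) and 308 (26.7%) also fell. Both changes are measured from the same day 1 control libraries, so part of this overlap may come from them. Independent lists of these sizes would share 163, 116 and 135 rising and 195, 155 and 176 falling genes. With phenetole 240 genes of the control time course changed in the opposite direction, against 4 and 2 with 9,10-dibutoxyanthracene and 4-phenoxybenzoic acid. More genes, the 169 rising and 308 falling ones, changed with phenetole in the same direction. The number of opposite genes from independent lists was not computed, so the 240 do not show that phenetole opposed the time course. The covariance across genes with the control time change was 1.898, 1.532 and 0.118, against 0.164, 0.161 and 0.146 in data simulated for unchanged groups, so that with phenetole the covariance did not exceed the simulated value.

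Each library was placed on the control time course from the 2251 genes that changed in it, with 0 for the day 1 and 1 for the day 3 control. At day 1, 4-phenoxybenzoic acid cultures stood at 0.75 ± 0.05 and 9,10-dibutoxyanthracene cultures at 0.91 ± 0.06 (SD, n = 3), while phenetole cultures at 0.06 ± 0.04 lay beside the control at 0.11 ± 0.16. At day 3, the positions were 0.74 ± 0.14 with phenetole, 1.02 ± 0.1 with 4-phenoxybenzoic acid, 1.17 ± 0.03 with 9,10-dibutoxyanthracene and 0.92 ± 0.07 in the control. In exact permutation tests against the control of the same day, p was 0.1 for both compounds at day 1 and for 9,10-dibutoxyanthracene at day 3, the smallest that 3 against 3 libraries can give. It was 0.9 and 0.2 for phenetole at days 1 and 3, and 0.3 for 4-phenoxybenzoic acid at day 3.

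**Figure D4:**
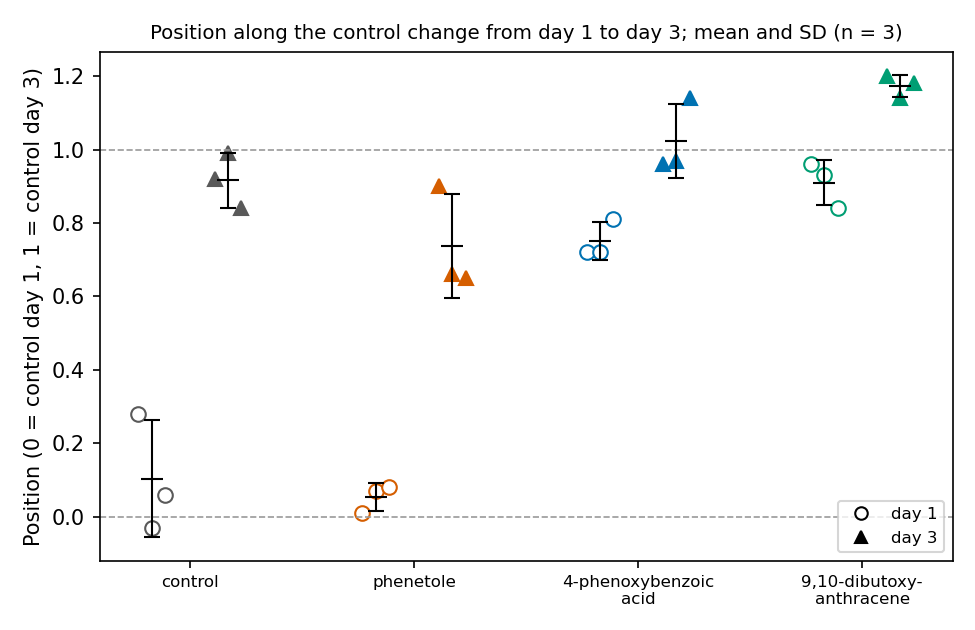
Position of each of the 24 libraries along the control change from day 1 to day 3 (no unit; 0 and 1 are the mean day 1 and day 3 controls, each control library placed on an axis made without it); points are libraries and bars are mean and SD of 3 flasks. At day 1, libraries with 4-phenoxybenzoic acid lay between 0.72 and 0.81 and those with 9,10-dibutoxyanthracene between 0.84 and 0.96, above all control libraries of that day (−0.03 to 0.28).

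The change from day 1 to day 3 itself differed from that of the control for many genes. Trisim1_002817 rose 178-fold with time in the control, while with 4-phenoxybenzoic acid it fell by 2.79 ± 0.69 on the log2 scale (adjusted p = 0.0339, edgeR). The difference between these changes passed the test for 4-phenoxybenzoic acid (adjusted p = 0.000226), phenetole (adjusted p = 0.00495) and 9,10-dibutoxyanthracene (adjusted p = 0.00647). Trisim1_008178 fell 19.7-fold with time in the control and differed by −0.31 ± 0.9 on the log2 scale between days with 9,10-dibutoxyanthracene; the difference between these changes had an adjusted p of 0.0281. For the neighbours Trisim1_006099 and Trisim1_006100 this difference did not pass the test with phenetole (adjusted p = 0.601 and 0.359). In all, edgeR called 2162 genes for phenetole, 1482 for 9,10-dibutoxyanthracene and 558 for 4-phenoxybenzoic acid. The phenetole count was 661 with only the compared groups in the fit and 1256 without day 3 control flask 3. The count for 4-phenoxybenzoic acid was 888 with DESeq2 and 209 without flasks numbered 3, that for 9,10-dibutoxyanthracene was 697 without these flasks, and 6 and 3 of 30 splits of the libraries gave as many genes as the real split of these compounds.

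The compounds were compared with each other at matched days, though their doses differed. Phenetole was added neat, while the other compounds share dichloromethane as solvent. At day 1 the diaryl ether 4-phenoxybenzoic acid and 9,10-dibutoxyanthracene differed in 8 genes by the edgeR test, of which 7 were lower and 1 was higher with 9,10-dibutoxyanthracene. Among the 7 were Trisim1_006099, lower by 688-fold (counting interval 123 to 27200; adjusted p = 0.0369), Trisim1_006100, lower by 126-fold (adjusted p = 0.003), and Trisim1_006101, at a log2 difference of −7.21 ± 0.78 (adjusted p = 7.89e-05). Trisim1_002817 was at −4.57 ± 0.75 (adjusted p = 0.0112). Trisim1_004508, named after its values were seen, was the gene that was higher with 9,10-dibutoxyanthracene (log2 difference 3.23 ± 0.61, adjusted p = 0.0397). At an unadjusted p under 0.05, 933 genes differed between them, DESeq2 called 62 (27 higher, 35 lower), and for 4819 genes (44.4%) the 95% interval of the difference lay within 2-fold. The count moved between 1 (without 9,10-dibutoxyanthracene flask 2 or flask 3) and 60 (without its flask 1), and without flasks numbered 3 edgeR called 0 (806 at an unadjusted p under 0.05; lowest adjusted p 0.0783).

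Phenetole differed at day 1 from 4-phenoxybenzoic acid in 5047 genes (2549 higher and 2498 lower with 4-phenoxybenzoic acid) and from 9,10-dibutoxyanthracene in 5183 genes (2622 higher and 2561 lower with 9,10-dibutoxyanthracene). Trisim1_003562 and Trisim1_003296, at a single count and at 0 counts with phenetole, were among the genes that rose with both other compounds. For the 3 neighbouring loci a difference between 4-phenoxybenzoic acid and phenetole did not pass the test at day 1. The log2 difference was −1.49 for Trisim1_006099 (95% interval −3.35 to 0.36; adjusted p = 0.175), −1.69 for Trisim1_006100 (−3.25 to −0.13; adjusted p = 0.0697) and −0.24 for Trisim1_006101 (−1.45 to 0.97; adjusted p = 0.756). At day 3, Trisim1_006101 was at −2.05 (−3.3 to −0.79; adjusted p = 0.0612). Trisim1_002817 was higher with 4-phenoxybenzoic acid than with phenetole at day 1, by 1.93 ± 0.67 on the log2 scale (adjusted p = 0.0229). Higher than in the control and in both other treatments at day 1 were 844 genes with phenetole, and 1008 were lower than in all 3.

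At day 3 the 9,10-dibutoxyanthracene cultures stood apart, with 4242 genes different from phenetole and 2143 different from 4-phenoxybenzoic acid. Trisim1_006101 stood at 0.258 ± 0.147 CPM with 9,10-dibutoxyanthracene, against 450 ± 261 with phenetole and 109 ± 82 with 4-phenoxybenzoic acid (SD, n = 3; adjusted p = 6.83e-07 and 2.82e-05, edgeR). Trisim1_001031 stood at 404 ± 19.4 CPM with 9,10-dibutoxyanthracene, 125 ± 98.4 with 4-phenoxybenzoic acid and 10.5 ± 9.32 with phenetole. Its difference from phenetole passed the test (adjusted p = 0.000475, edgeR), while that from 4-phenoxybenzoic acid did not (log2 difference 1.69 ± 0.85, adjusted p = 0.163). Lower than in the control and in both other treatments were 697 genes with 9,10-dibutoxyanthracene, and 328 were higher than in all 3. Between 4-phenoxybenzoic acid and phenetole 408 genes differed, 182 higher and 226 lower with 4-phenoxybenzoic acid. That count was 841 with DESeq2, 0 by edgeR on the compared groups alone (2136 at an unadjusted p under 0.05), and between 27 (without 4-phenoxybenzoic acid flask 3) and 645 (without phenetole flask 1). The count against 4-phenoxybenzoic acid moved to 825 without 4-phenoxybenzoic acid flask 2, 831 without its flask 1, 939 without 9,10-dibutoxyanthracene flask 3 and 1052 without its flask 2.

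The genes called with 4-phenoxybenzoic acid and with 9,10-dibutoxyanthracene overlapped at day 1. Both compounds were added in dichloromethane and phenetole was added neat, so the overlap cannot be told apart from a response to the solvent. Trisim1_003562 and Trisim1_001031 were among 957 genes that rose with both, and Trisim1_008178 and Trisim1_010012 among 1212 that fell with both; 0 changed in opposite directions. Independent lists of these sizes would share 170 and 246. The covariance of the log2 changes across genes was 1.904, against 0.16 in 20 data sets simulated for unchanged groups against the same controls. Phenetole shared 137 rising and 317 falling genes with 4-phenoxybenzoic acid, where independent lists would share 141 and 222, and 395 genes changed in opposite directions. It shared 232 rising and 401 falling genes with 9,10-dibutoxyanthracene, against 199 and 279, with 416 opposite. How many opposite changes independent lists would give was not computed for either pair. The covariance of its changes with theirs was 0.129 and 0.157, against 0.161 and 0.161 in the simulated data, so it did not exceed the simulated value. Deviations shared by flasks of the same number were not simulated, which can set the simulated value too high. With all 3 compounds at day 1, 114 genes rose and 287 fell, and 2454 genes changed the same way with 2 or 3 compounds. At day 3 phenetole and 9,10-dibutoxyanthracene shared 1 rising and 54 falling genes and 69 changed in opposite directions, with a covariance of −0.159 against 0.147 in the simulated data. The covariance was 0.313 against 0.146 for phenetole with 4-phenoxybenzoic acid (2 genes rose and 3 fell with both, 0 opposite), and 0.215 against 0.147 for 4-phenoxybenzoic acid with 9,10-dibutoxyanthracene (0 rose and 3 fell with both, 1 opposite). As genes were simulated independently, the simulated data do not give the spread of the covariance for genes that vary together. Whether these gaps at day 3 exceed that spread was not tested. The number of genes that changed the same way with 2 or 3 compounds was 59 at day 3 (191 by DESeq2 calls), and the genes that fell with all 3 compounds were Trisim1_004314 and Trisim1_009862, named after their values were seen.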

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

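The tests of the solvent, of swapped libraries, of the position from separate control libraries and of the position without the most abundant genes were chosen after the data were seen; the others were planned before. The following results met a planned criterion, a change between days that differed between cultures with a compound and control cultures by a test of the difference itself (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per group). The numbers of genes were 2162 for phenetole, 558 for 4-phenoxybenzoic acid and 1482 for 9,10-dibutoxyanthracene. Among the named genes, Trisim1_002817 had differences of −6.63 ± 1.44 with phenetole, −10.05 ± 1.38 with 4-phenoxybenzoic acid and −6.2 ± 1.46 with 9,10-dibutoxyanthracene on the log2 scale. Trisim1_001031 had −5.57 ± 1.56 with 4-phenoxybenzoic acid and −4.76 ± 1.57 with 9,10-dibutoxyanthracene, and Trisim1_006101 had −4.17 ± 1.12 with 9,10-dibutoxyanthracene. Trisim1_007510 had 3.48 ± 0.99 with 4-phenoxybenzoic acid, and Trisim1_008178 had 3.99 ± 1.14 with phenetole and 4.05 ± 1.21 with 9,10-dibutoxyanthracene. Among genes of the control time course, Trisim1_003562 had −8.55 ± 0.89 with 4-phenoxybenzoic acid and −10.64 ± 0.86 with 9,10-dibutoxyanthracene, and Trisim1_003296 had −8.45 ± 2.47 with 9,10-dibutoxyanthracene. Trisim1_009558 had 6.45 ± 2.23 with phenetole, 9.98 ± 2.45 with 4-phenoxybenzoic acid and 9.21 ± 2.09 with 9,10-dibutoxyanthracene. The control groups of Trisim1_002817, Trisim1_003562, Trisim1_003296 and Trisim1_009558 include a group with 0 to 2 counts, so the fitted sizes of their differences depend on the prior count and are no bounds.

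Day 1 cultures with 4-phenoxybenzoic acid or 9,10-dibutoxyanthracene lay toward the day 3 control, with Trisim1_003562 and Trisim1_003296 already up and Trisim1_007370 already down. Shared control libraries could produce such a shift, but with the origin and the axis taken from separate control libraries the lowest of the 6 libraries still stood at 0.75, against at most 0.24 in the day 1 control. Without the 100 most abundant genes the lower group mean was again 0.75. That test decides little about abundant genes. The position weights genes by their log2 change in the control and not by abundance, so leaving out at most 100 of 2251 genes could hardly move it. Dichloromethane, the solvent of both stocks, stays open: it would make up 5% of the volume with 4-phenoxybenzoic acid and 2.5% with 9,10-dibutoxyanthracene, and the cultures with less of it stood 0.16 further along, but dose and compound differ as well, so solvent and compound cannot be told apart. A response to the compounds themselves stays open as well and was not tested apart from the solvent, which would need controls with dichloromethane alone. The same holds for copper, manganese and veratryl alcohol if the control did not receive them.

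With phenetole many genes changed at day 1 and few at day 3, with Trisim1_006099 and Trisim1_006100 high at both. A gene length bias between libraries could raise the day 1 count, but after the length trend of each library was removed 2935 genes were called, against 2988. A few abundant genes, or the scaling they set, could raise it too, but without the 100 most abundant genes 2850 were called. Leaving out 100 genes can remove at most 100 calls directly, so that count bears mainly on the scaling, which was recomputed without them. A swap of libraries between phenetole and control at day 1 would place a library nearer the other group, and 6 of 6 libraries were nearer their own; the closest case was control flask 3, at 0.89 from its own group and 1.04 from phenetole. A response to phenetole that differs between days stays open, and residual phenetole was not analysed here. The treatment text also lists copper, manganese and veratryl alcohol, and whether the control received them is not given. If it did not, a response to these additions cannot be told apart from one to phenetole.

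Flasks with the same number deviated together across groups, weakly on average (mean correlation across genes 0.1 for the same number and −0.05 for other numbers over 28 pairs of groups) and above 0.1 for all 3 numbers in 2 of 16 comparisons. For flask number, 659 genes were called with groups as terms, of which 453 were higher and 206 lower in flask 3 than in flask 1. Among 100 numberings within the groups only 1, the real one, called as many (highest other 45). Numbers unrelated in all 8 groups are thus excluded as the cause. The numbers were shuffled in each group and day apart. If a flask was sampled at both days, that alone could set the real numbering apart, so chance numbering across compounds is not excluded. Depth could produce the shared deviations, but the mean log2 total count of flasks 3 and 1 differed by −0.042, and after removal of each library's length trend 687 genes were called. Trisim1_008911 (711 bp), named after its values were seen, was higher in flask 3 than in flask 1 in all 8 groups, by 0.48 to 2.56 on the log2 scale. A handling or sequencing order shared by flasks of the same number is not given in the sources used here, and no biological explanation was tested.

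For 3 against 3 libraries there are 10 splits, the real one included, which is too few for a share under 0.05; in each of these comparisons 1 split, the real one, gave as many genes. Against the control, the real count and the highest other were 2988 and 1407 with phenetole, 2601 and 0 with 4-phenoxybenzoic acid and 3442 and 1 with 9,10-dibutoxyanthracene at day 1. They were 371 and 12, 8 and 2, and 1740 and 0 at day 3, in the same order. The split with 1407 genes placed control flask 3 with phenetole flasks 2 and 3 and points to a structure among these libraries. For day 3 against day 1 they were 2251 and 67 in the control, 4936 and 14 with phenetole, 329 and 0 with 4-phenoxybenzoic acid and 2354 and 0 with 9,10-dibutoxyanthracene. Between compounds at day 1 they were 5047 and 0 for 4-phenoxybenzoic acid against phenetole, 5183 and 1 for 9,10-dibutoxyanthracene against phenetole, and 8 and 0 for 9,10-dibutoxyanthracene against 4-phenoxybenzoic acid. At day 3 they were 408 and 1, 4242 and 0, and 2143 and 2, in the same order. For the difference of the time changes 30 splits were drawn, and 1 of 30, the real one, gave as many genes for phenetole (2162, highest other 2092). For 4-phenoxybenzoic acid 6 of 30 did (558, highest other 1091) and for 9,10-dibutoxyanthracene 3 of 30 did (1482, highest other 2008). The planned limit, a share under 0.05, was thus met for phenetole, by 2162 against 2092 genes, and not for the other compounds. Swapping the labels at 1 day only turns the difference between cultures into a difference of time changes, so such splits can call many genes by construction. As these splits do not mimic chance alone, chance is not called excluded for any of the 3 compounds.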

How the results depend on the processing

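The fits without flasks numbered 3 and the position from separate control libraries or without the most abundant genes were chosen after the data were seen; the other alternatives were planned. Replacing TMM by DESeq2 size factors (which moved the median change by at most 0.051 on the log2 scale), dropping the filter, and limma on log2(FPKM + 0.1) left all 19 counts within 1.5 times their value, and 0 named calls reversed under any alternative. Over the alternatives other than leaving out a library, 140 values kept their size or side, 20 were lower, 10 higher and 2 positions moved by more than the SD; of the named calls 198 held and 26 were lost. Of the values that changed, the cause was not tested. Fits of fewer libraries have less power by construction. The main fit also shares a spread estimate among groups whose spread differed. At day 1 the median SD of log2 CPM over genes was 0.495 with phenetole and 0.485 in the control. It was 0.28 with 4-phenoxybenzoic acid and 0.309 with 9,10-dibutoxyanthracene. The shared estimate may thus be too small for phenetole against control at day 1. Counting limits genes near 0 counts, whose folds are bounds or carry wide intervals. In what follows, A is 4-phenoxybenzoic acid, D is 9,10-dibutoxyanthracene, P is phenetole and C is control.

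With the DESeq2 Wald test the counts were 908 for P against C at day 3, 181 for A against C at day 3, 731 for the time change with A, 888 for its difference from the control's, 62 for D against A at day 1, 841 for A against P at day 3, and 191 for genes shared by 2 or 3 compounds at day 3. With limma on log2(FPKM + 1) the count for D against A at day 1 was 15. With only the compared groups in the edgeR fit they were 609 for P against C and 2209 for D against C at day 1, 11 for P against C and 0 for A against C at day 3 (1114 at an unadjusted p under 0.05), 1228 for the control time change, 661 for its difference with P, 5 for D against A at day 1 and 0 for A against P at day 3 (2136 unadjusted). With the flask number as a block they were 678 for P against C and 133 for A against C at day 3. Without flasks numbered 3 they were 1285 for A against C and 2162 for D against C at day 1; 19, 0 (540 unadjusted) and 714 for P, A and D against C at day 3; 1459, 24 and 1375 for the time change in C, A and D; 209 and 697 for its difference with A and D; and, by edgeR, 0 for D against A at day 1 (806 unadjusted) and 0 for A against P at day 3 (872 unadjusted). From separate control libraries the position was 1.26 for D at day 3 and −0.04 for P at day 1.

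With a library left out in turn, counts against C at day 1 ranged from 1869 (without C flask 2) to 3418 for P, from 1704 (without A flask 1) to 2933 for A and from 2509 to 3482 for D. At day 3 they ranged from 82 (without P flask 3; 141 without P flask 2, 100 and 221 without C flasks 2 and 3) to 470 for P, from 1 (without C flask 3; 2 without C flask 2, A flask 2 or A flask 3) to 81 (without C flask 1) for A, and from 729 (without D flask 2; 799 without D flask 3, 907 without C flask 2) to 1389 for D. For the time change they ranged from 1670 to 2358 in C, from 3984 to 4840 in P, from 30 to 318 in A (30, 43 and 159 without day 1 flasks 1, 2 and 3; 190 and 64 without day 3 flasks 2 and 3) and from 1358 (without D day 3 flask 3; 1404 without day 1 flask 2, 1500 without day 3 flask 2) to 1869 in D. For its difference from the control's they ranged from 1256 (without C day 3 flask 3) to 2847 for P, 395 to 661 for A and 1050 to 1962 for D. Between compounds at day 1 they ranged from 4109 to 5049 for A against P, 4285 to 5060 for D against P, and 1 (without D flask 2 or 3; 5 without A flask 2 or 3) to 60 (without D flask 1) for D against A. At day 3 they ranged from 27 (without A flask 3; 74 and 53 without P flasks 2 and 3) to 645 (without P flask 1) for A against P, 3122 to 3710 for D against P, and 825 (without A flask 2; 831 without A flask 1, 1052 and 939 without D flasks 2 and 3) to 2493 for D against A. With a control library left out in turn, positions ranged from 0 to 0.14 for P, 0.7 to 0.8 for A and 0.85 to 0.93 for D at day 1, and from 0.7 to 0.78, 0.96 to 1.04 and 1.11 to 1.18 at day 3; libraries with a compound were not left out for the positions. With a library of the compared groups left out, 136 of the named calls held and 32 were lost, 0 of them at day 1 or in the control time course.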

Other observations

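All tests in this part were planned before their results were seen, except the comparison of day 1 cultures with the day 3 control, which was added after. With 4-phenoxybenzoic acid at day 1, Trisim1_006102, next in the numbering to Trisim1_006101 and named after its values were seen, rose by 4.15 on the log2 scale (adjusted p = 0.000133, edgeR), but with phenetole at day 1 it differed by −0.24 (adjusted p = 0.829). With 9,10-dibutoxyanthracene, where Trisim1_006100 had 58 counts over the libraries of day 1 and 11 over those of day 3, Trisim1_006102 rose by 3.02 at day 1 (adjusted p = 0.00118) and 2.67 at day 3 (adjusted p = 0.00504). Set against the day 3 control, day 1 cultures differed in 242 genes with 9,10-dibutoxyanthracene, 578 with 4-phenoxybenzoic acid and 4551 with phenetole by the edgeR test.

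Genes numbered next to each other may respond together in clusters, as the run of Trisim1_006099, Trisim1_006100 and Trisim1_006101 shows for a single place. For the 12 lists of genes that rose or fell with a compound at a day, adjacent pairs were counted and compared with 10000 random placements among the tested gene models. In 11 of 12 lists the pairs exceeded those of 95% of the placements. Among these, the list of 4 genes that rose with 4-phenoxybenzoic acid at day 3 held a single pair, Trisim1_006100 and Trisim1_006101. That pair belongs to the run named above, so this list adds no separate evidence. The other lists are not independent either. Comparisons of a day share control libraries, and 4-phenoxybenzoic acid and 9,10-dibutoxyanthracene shared 957 rising and 1212 falling genes at day 1. The 11 lists are thus not 11 separate results. Among genes that rose with phenetole at day 1 there were 283 adjacent pairs against 124.4 on average at random, and among those that fell with 4-phenoxybenzoic acid at day 1 there were 357 against 166 (permutation p = 1e-04 for each, the smallest that the placements can give). The exception was the list of 4 genes that fell with 4-phenoxybenzoic acid at day 3, with 0 pairs. The longest run was 10 gene models, Trisim1_000730 to Trisim1_000739, which fell with 4-phenoxybenzoic acid and with 9,10-dibutoxyanthracene at day 1. Numbers stand for order in the annotation, and whether they follow chromosome order is not given in the sources used here; reads shared between neighbouring models were not analysed.

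That loci outside the numbered gene models respond more often than the gene models was tested as a hypothesis. The called share was larger among them in 0 of 6 comparisons with the control. It was 22.6% against 27.9% with phenetole, 17.7% against 24.4% with 4-phenoxybenzoic acid and 24.8% against 32.2% with 9,10-dibutoxyanthracene at day 1 (Fisher's exact test, adjusted p = 0.0072, 0.00025 and 0.00025). At day 3 it was 13% against 16.2% with 9,10-dibutoxyanthracene (adjusted p = 0.046, same test). With phenetole it was 2.79% against 3.46% (adjusted p = 0.52) and with 4-phenoxybenzoic acid 0% against 0.0785%, differences that did not pass. Loci outside the models were 645 of the 10842 tested loci but held only 1.08% to 3.02% of the counts of a library. They thus had fewer counts on average, which lowers the power to call them. The loci were not matched for counts or length and were treated as independent. Whether they respond less often than the gene models is therefore not settled.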
